A study of Caenorhabditis elegans with 2 samples.

How the data were processed

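The data were peak lists from ChIP-seq of GFP-tagged SNPC-1.3 in whole young adult hermaphrodites of C. elegans, in 2 samples labelled as biological replicates 1 and 2 of the same strain. Per the text notes deposited with the lists, the regions of each replicate were called from that replicate's alignments against 1 control, the pooled regions from both replicates together against the same control, and the IDR peaks from both replicate lists with the pooled list. The aligner, the peak caller, the IDR threshold, the read length and the read counts are not given in the sources used here. Each list was deposited on ce10 and on ce11. The deposited lists hold a signal value per region, in the unit of the authors' caller, and the deposited −log10 q-value; the p-value column was filled with a placeholder throughout. Signal values were used only to rank, filter or describe regions within a list, since the scales of the lists differ. The candidate lists were 30000 regions each, and 99.3% of the pooled regions had the same width of 276 bp, so that neither the length of a list nor most widths carry information on depth. Depth per sample is therefore unknown, and the number of peaks, not of reads, sets the precision given here. Replicates are separate biological samples per the labels; tests over regions treat regions as independent and describe these 2 replicates pooled.

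The ce11 lists were analysed with the Ensembl release 115 annotation and a RefSeq genome sequence of the same assembly, WBcel235, on which all chromosome lengths were checked to hold every region. The starts of regions were converted to 1-based positions. Classes were taken from annotated biotypes of nuclear genes, SL RNA genes from their sls names, tRNA isotypes and tRNA pseudogenes from RefSeq, and snRNA kinds from sequence. A region was assigned to an RNA gene when its summit was in the gene or within 250 bp of it, and to a protein-coding promoter when it was within 500 bp of the annotated 5′ end. The classes overlap, except where each peak was given a single class, in the order tRNA, snRNA, SL RNA, rRNA, snoRNA, other short non-coding RNA of up to 500 bp, piRNA, miRNA, protein-coding promoter, gene body and none.

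For each class the 1676 IDR peaks were compared with the 28324 other pooled candidates by a 2-sided Fisher's exact test, with Woolf 95% intervals of the odds ratio (0.5 added to each cell where a cell was 0) and Benjamini-Hochberg adjustment over the 9 classes. Mitochondrial regions stayed in these tables as outside every class. Shares of loci have Clopper-Pearson 95% intervals, which cover counting error only. Agreement of the replicates was tested with 100000 circular shifts along each nuclear chromosome, and the class counts against shifted IDR peaks with 100000 shifts. Gene lists were tested among protein-coding genes with a candidate summit within 500 bp, adjusted over 17 lists. Motifs were searched on both strands within 100 bp of nuclear summits and in windows of equal length 500 bp to each side, with an exact McNemar test against each side, and the larger p is given. The piRNA bins were 100 kb bins of chromosome IV with at least 20 piRNA genes. The tests of replicate agreement, of the classes, of the piRNA bins, of tRNA genes by isotype and by X against autosomes, of the gene lists and of the motifs CTGTTTCA and GWTCRANNC, the lists themselves and the rule for naming genes were fixed before the data were examined. The test of U6 against the other kinds, planned as a count, and the tests of low-ranked candidates against shifts, of unique 31-mers and of mitochondrial summits inside tRNA genes were added later, before their own results were known. Chosen after results were seen were the tests of the motif AACNNNNNNNNTGTC, which are 11 of the 33 motif tests adjusted together, of rank bands, of X against autosomes among unique loci, of mitochondrial coverage, of mitochondrial summits within 100 bp of tRNA genes and of local shifts with matched GC content. That rule took the 20 IDR peaks of highest signal, the 5 loci per RNA class and the 4 members per list with the peaks of highest signal, and the genes snpc-1.3 and unc-119. The top mitochondrial peaks are described together.

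Alternatives were the 838 IDR peaks of highest signal, windows of 0.5 and 2 times the size, any overlap in place of summits, circular shifts as background, the candidates of each replicate alone, other bin rules and other motif windows. Alternatives without mitochondrial regions and without regions at short RNA genes were chosen after seeing the data. Low-ranked candidates were compared with shifts of 1 to 5 kb within the piRNA-rich bins (10000 draws), and with shifts whose 201 bp window had a GC content within 2 percentage points. Near-identical copies were measured as the share of 31-mers in a locus window that occur once in the genome on either strand; 31 bp stands in for the read length, which is not given in the sources used here.

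The code was tested on simulated data. With the real 30000 candidates and a class simulated at an odds ratio of 10, the class test called it in 20 of 20 runs with a median odds ratio of 10.0, and made 1 call in 120 tests of classes with no effect. The gene list test called the enriched list in 20 of 20 runs and made 2 calls in 320 tests of other lists. Of 1676 simulated regions of which 60% were shared, 60.3% were recovered, and 0 of 20 unrelated pairs passed. A motif planted in 30% of 1000 windows was found in 27% above the flanks, and local shifts with 200 planted summits gave a ratio of 1.25 where 1.29 was expected, so both recovered slightly less than was put in. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.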

Results

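Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult hermaphrodites of Caenorhabditis elegans. The strain, YL485, expressed SNPC-1.3 (gene F08F3.9) with GFP and FLAG tags at its C terminus, and the tagged protein was precipitated with an antibody against GFP from sonicated chromatin. SNPC-1.3 is a paralogue of a subunit of SNAPc, the complex that recruits RNA polymerases to the promoters of small nuclear RNA (snRNA) and spliced leader (SL) RNA genes and, in nematodes, of piRNA genes; it is known as a piRNA transcription factor of the male germline. The series held 1 group of 2 biological replicates. For each genome build the files held 30000 candidate regions per replicate, 30000 candidate regions from the pooled replicates, and a list of regions that passed an irreproducible discovery rate (IDR) threshold, here called IDR peaks. Read depth was unknown, because the lists carry no read counts, and all 3 candidate lists had the same length. All coordinates below are 1-based positions on ce11. With no second group, every comparison is between regions or gene classes, not between conditions.

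In ce11 1676 IDR peaks were listed, 1650 on the nuclear chromosomes and 26 on the mitochondrial genome. Peaks were densest on chromosome III, at 23.8 per Mb, and sparsest on chromosomes V and X, at 10.1 and 10.9 per Mb. Chromosomes I, IV and II had 19.8, 19.7 and 17.9 per Mb. The authors' signal value of the IDR peaks ran from 39.8 to 7841 with a median of 57.8, and the highest value on a nuclear chromosome was 411. The median width was 276 bp. The IDR peaks were the 1676 regions of highest signal in the pooled candidate list. The other build, ce10, gave 1658 IDR peaks with a median signal of 58.3, and no coordinates were carried between the builds.

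The replicates ranked many of the same regions at the top. Of the 1676 regions of highest signal in replicate 1, 998 (59.5%) overlapped one of the 1676 regions of highest signal in replicate 2 by at least 1 bp. Circular shifts of replicate 2 along each nuclear chromosome gave a mean of 2.54% and at most 15% (permutation p = 1e-05, 1-sided, the smallest that 100000 shifts can give). Both replicates were called against the same control, and the shifts do not keep any agreement that comes from it. Of the 1676 IDR peaks, 981 overlapped a top region of both replicates and 66 a top region of neither. Across the 1649 IDR peaks with a candidate in both replicates, the ranks correlated with a Spearman rho of 0.468, a value across regions within 1 pair of replicates.

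The 18 peaks of highest signal were mitochondrial, so the nuclear peaks of highest signal are described as well, a choice made after the values were seen. The top nuclear peaks lay upstream of ribosomal protein genes and of small nucleolar RNA (snoRNA) genes. The highest (signal 411, chromosome IV 654823 to 655025) had its summit 349 bp upstream of rpl-15, outside any protein-coding gene. The next (signal 375, IV 4749964 to 4750177) lay between the divergent genes Y17G9B.5 and rpl-20, with its summit 157 bp upstream of the former and 305 bp upstream of the latter. Peaks upstream of rpl-3 (signal 341, III 3867480 to 3867668), of cdc-48.1, which encodes an AAA ATPase of protein quality control (signal 301, II 10563475 to 10563660), and of rpl-35 (signal 277, III 7854611 to 7854786) followed. The sixth was 40 bp upstream of the snoRNA gene ZK994.7 in an intron of pxn-1 (signal 276, V 8500453 to 8500622). The seventh was 53 bp upstream of the SL2-type gene sls-2.8 (signal 265, III 12250308 to 12250489). All 7 ranked within the top 42 candidates of replicate 1 and the top 31 of replicate 2.

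The class at the summit changed with rank. Among the top 50 nuclear peaks, 25 were at snoRNA genes, 15 at promoters of protein-coding genes and 0 at tRNA genes, when each peak was given a single class in a fixed order with short RNA genes ahead of promoters. Among all 1650 nuclear peaks, 742 (45%) were at protein-coding promoters, 317 (19.2%) at tRNA genes, 86 (5.21%) at snoRNA genes, 83 at other annotated short non-coding RNA genes, 33 at snRNA genes and 14 at SL RNA genes. A further 148 lay elsewhere in gene bodies and 196 had no gene at the summit. The median signal was 111 at snoRNA genes, 104.4 at SL RNA genes, 68.8 at snRNA genes, 62.3 at tRNA genes and 55.5 at protein-coding promoters.

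**Figure D1:**
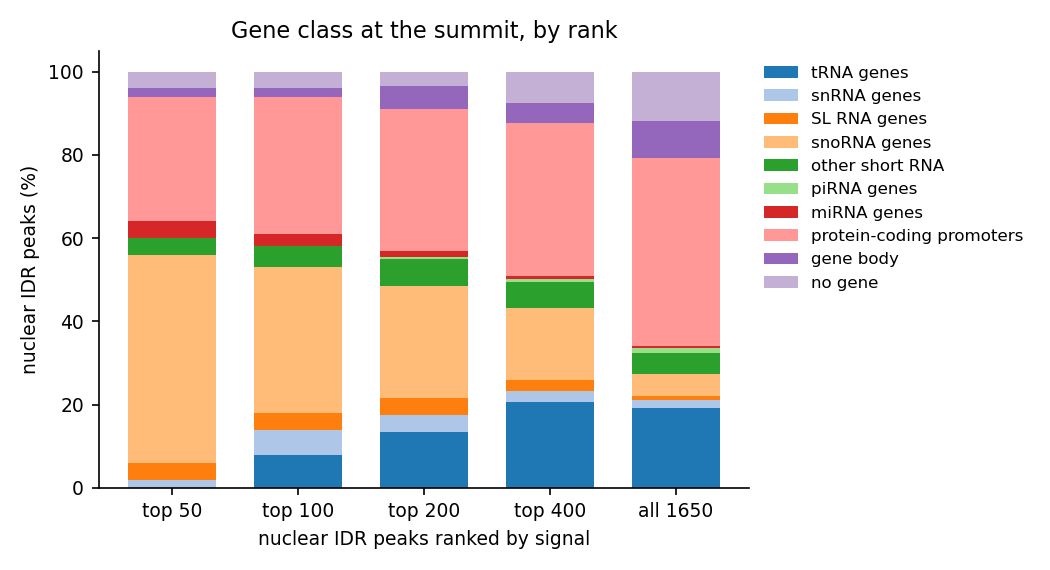
Stacked bars show the percentage of nuclear IDR peaks given to each gene class (y axis) among the top 50, 100, 200 and 400 peaks by signal and among all 1650 (x axis). snoRNA genes held 25 of the top 50 peaks, and tRNA genes 0 of the top 50 and 82 of the top 400.

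Whether short RNA genes, only some of them known targets of SNAPc or of RNA polymerase III, were over-represented was asked by comparing the 1676 IDR peaks with the 28324 other pooled candidates. tRNA, SL RNA, snRNA, snoRNA and miRNA genes and protein-coding promoters were enriched, and piRNA genes were depleted (2-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 9 classes). A summit within 250 bp of a tRNA gene was found for 317 IDR peaks (18.9%) and 155 other candidates (0.547%), an odds ratio of 42.4 (95% interval 34.7 to 51.8, exact test, adjusted p = 7.07e-285). For SL RNA genes the counts were 15 and 7 (odds ratio 36.5, 14.9 to 89.7, exact test, adjusted p = 3.21e-14), for snRNA genes 33 and 33 (17.2, 10.6 to 28.0, adjusted p = 8.98e-24), and for snoRNA genes 87 and 112 (13.8, 10.4 to 18.3, adjusted p = 7.87e-55). miRNA genes gave 15 and 49 (odds ratio 5.21, 2.92 to 9.31, adjusted p = 2.31e-06). The odds ratio of SL RNA genes was 79.5 without replicate 1, 85.3 with 0.5 times the window and 63.7 with the 838 peaks of highest signal, and that of snoRNA genes 25.1 with those 838 peaks. For miRNA genes it was 3.24 without replicate 1, 3.14 without replicate 2, 2.71 with 2 times the window and 3.23 with any overlap of the region, and passed the exact test in each. tRNA pseudogenes gave 8 and 68 (1.99, 0.956 to 4.15) and did not pass the exact test (adjusted p = 0.0831), but passed with a window of 0.5 times the size (odds ratio 2.95, adjusted p = 0.0110), with the candidates of replicate 1 alone (2.73, adjusted p = 0.0111) and against circular shifts (4.84-fold, adjusted p = 0.00159). No IDR peak and 1 other candidate lay at the 20 nuclear rRNA genes (exact test, adjusted p = 1).

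Each replicate gave similar shares. Among the 1676 top regions of each replicate, tRNA genes held 298 in both, 17.8% ± 0 (SD, n = 2). The shares were 5.25% ± 0.253 (SD, n = 2) for snoRNA genes, 1.91% ± 0.253 for snRNA genes, 0.835% ± 0 for SL RNA genes, 2.48% ± 0.0422 for piRNA genes, 0.656% ± 0.0844 for miRNA genes, 0.0298% ± 0.0422 for rRNA genes, 0.477% ± 0.0844 for tRNA pseudogenes and 49.8% ± 3.8 for protein-coding promoters.

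Counted by locus, 349 of 612 tRNA genes had an IDR peak (57.0%, Clopper-Pearson 95% interval 53.0 to 61.0%). The share was 62.0% on the X chromosome (171 of 276) and 53.0% on the autosomes (178 of 336), an odds ratio of 1.45 (1.046 to 2.00, Fisher's exact p = 0.0270) that was 1.31 (p = 0.103) with a window of 0.5 times the size. Neighbouring tRNA genes can share a peak, while this test treats loci as independent. By autosome the share ran from 37.2% on chromosome V (29 of 78) to 67.6% on chromosome IV (48 of 71), which was not tested. Shares by isotype ran from 35.7% for tRNA-Phe (5 of 14) to 75% for tRNA-Trp (9 of 12) among isotypes with over 1 gene, and no isotype differed from the rest after adjustment (smallest adjusted p = 0.536, Fisher's exact test). The strongest peak at a tRNA gene (signal 147, X 3036009 to 3036284) lay between the divergent genes M02F4.t1, a tRNA-Gly gene with 29 copies of its sequence in the genome, and M02F4.t2, a tRNA-Glu gene with 20, so these loci are uncertain. T07H6.t1, a tRNA-Ala gene with 8 copies, in an intron of lev-9 (X 6286321 to 6286392), had a peak of signal 133, and T23F1.t1 and T23F1.t2, of tRNA-Lys and tRNA-Pro (14 and 24 copies), shared a peak of signal 130.4 (V 15465038 to 15465313).

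Among snRNA genes 32 of 99 loci had an IDR peak (32.3%, 23.3 to 42.5%). U5 and U1 genes had them most often, at 9 of 12 (75%) and 9 of 13 (69.2%). They were followed by U4 genes at 2 of 5 and by genes of the nematode smY family annotated as snRNA at 4 of 10. Among these, smy-1 had its summit 302 bp downstream of its 5′ end. The genes smy-2 and smy-3, annotated as snoRNA genes, also had a peak and are counted in that class. U2 genes had 4 of 20 (20%) and U6 genes, which unlike the other kinds named here are transcribed by RNA polymerase III, 3 of 23 (13.0%, 2.78 to 33.6%). U6 loci had a peak less often than U1, U2, U4 and U5 loci together (odds ratio 0.163, 0.0428 to 0.617, Fisher's exact p = 0.00429). The strongest were at sup-6, a U1 gene in an intron of F58G1.7 (signal 158, II 12944803 to 12944967), F32B5.9, a U5 gene in an intron of cpz-1 (144, I 2688947 to 2689069), Y57G11C.35, a U2 gene in an intron of Y57G11C.5 (142, IV 14764848 to 14765034), H27M09.6, a U1 gene (135, I 6847137 to 6847303), and T11F9.15, a U4 gene with 2 copies (131, V 11980118 to 11980261). The kinds were read from sequence, and 16 of the 99 loci could not be given a kind, with a peak at 1 of them (6.25%). The comparison of U6 with the other kinds leaves these loci out. Identical or near-identical copies make single loci of U1, U2, U5 and U6 uncertain.

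SL RNA genes split by kind. SL2-type genes had a peak at 14 of 18 loci (77.8%, 52.4 to 93.6%), led by sls-2.8 (signal 265), sls-2.1 (161, II 5844865 to 5844974), sls-2.16 in an intron of glr-2 (138, III 7141391 to 7141499), sls-2.15 in an intron of W09D6.5 (127, III 11091010 to 11091121) and sls-2.9 (120.4, I 13297877 to 13297985), whose summit was also within 250 bp of a tRNA gene. SL1 genes, which carry only 2 distinct sequences over 12 annotated loci, had none (0 of 12, upper limit 26.5%).

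**Figure D2:**
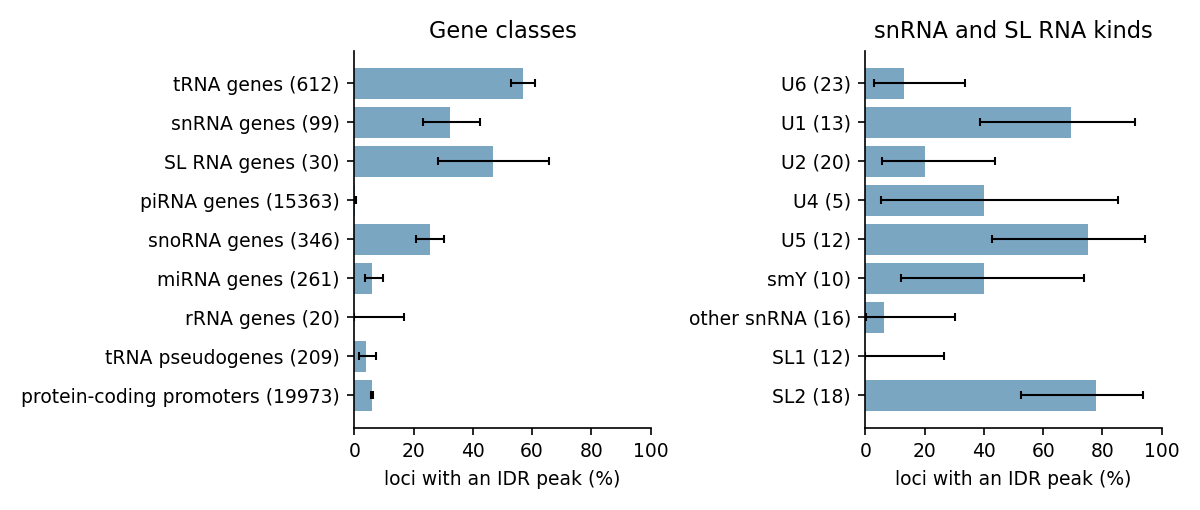
Bars show the percentage of annotated loci with an IDR peak (x axis) for each gene class and for each kind of snRNA and SL RNA gene, with the number of loci in brackets and Clopper-Pearson 95% intervals as error bars. SL2 genes reached 77.8% and SL1 genes 0%, and piRNA genes 0.338%.

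At 88 of 346 snoRNA genes there was an IDR peak (25.4%, 20.9 to 30.4%), and after ZK994.7 the strongest were at Y53F4B.47 (signal 257, II 15025814 to 15025893), C16D9.11 in an intron of rol-3 (239, V 8228900 to 8228969), C08D8.3 in an intron of C08D8.1 (227, V 8349108 to 8349187) and T08B6.64 (209, IV 4880738 to 4880850). Of 261 miRNA genes 16 had a peak (6.13%, 3.54 to 9.76%). The strongest were cel-mir-8196b in an intron of prx-1 (signal 217, X 14324355 to 14324517), cel-mir-5549 (150, III 6971976 to 6972085) and cel-mir-8196a (140, X 2328994 to 2329124), while cel-mir-51 and cel-mir-4936 followed at 68.03 and 64.02. The cel-mir-5549 peak was also 378 bp upstream of eef-1A.1. tRNA pseudogenes had a peak at 8 of 209 loci (3.83%), the strongest at D1046.t1 in an intron of cfim-2 (signal 144), where the summit was also within 250 bp of a snoRNA gene. The 20 rRNA genes had none (upper limit 16.8%, for independent loci), but 17 of them had under 80% unique 31-mers (median 6.66% over the 20), so these near-identical copies are uncertain.

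Summits took different places in different classes. They lay upstream of the annotated 5′ end at 14 of 14 SL RNA genes (median -55.5 bp), at 78 of 88 snoRNA genes (median -41.5 bp) and at 22 of 32 snRNA genes (median -23 bp). At tRNA genes the median was 24 bp downstream of the 5′ end, inside the gene, with the summit upstream at 29.8% of 349 loci. At protein-coding genes it was upstream at 1074 of 1187 loci (median -192 bp). A summit shared by neighbouring loci was counted at each of them. These positions were described without a test.

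**Figure D3:**
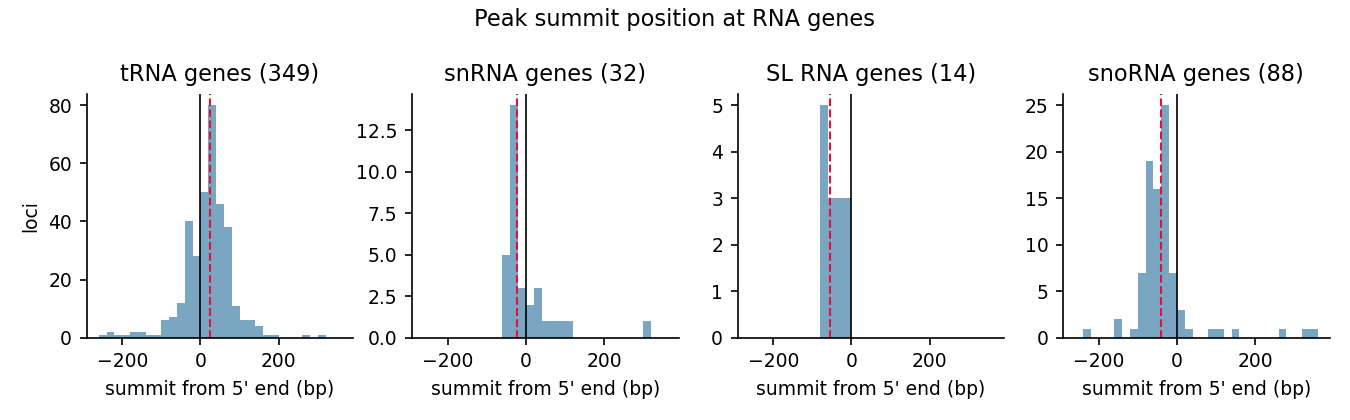
Histograms give the number of loci (y axis) by the position of the peak summit relative to the annotated 5′ end of the gene in bp (x axis, negative upstream; the solid line marks 0 and the dashed line the median). tRNA summits centred inside the gene at 24 bp, and SL RNA, snoRNA and snRNA summits upstream at -55.5, -41.5 and -23 bp.

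piRNA genes, the targets for which the SNPC-1.3 protein is known in males, held few of the IDR peaks in these hermaphrodites. A summit within 250 bp of a piRNA gene was found for 41 IDR peaks (2.45%) and 1820 other candidates (6.43%), an odds ratio of 0.365 (0.267 to 0.4997, Fisher's exact test, adjusted p = 3.98e-13). Circular shifts of the IDR peaks placed 71.1 there on average (0.577-fold, permutation adjusted p = 0.00601). Of 15363 piRNA genes, 52 (0.338%, 0.253 to 0.444%) had an IDR peak, and 20 of the 41 peaks were not at a tRNA, snRNA, SL RNA, snoRNA or other short RNA gene. The highest were at loci shared with other genes. The pair 21ur-7591 and 21ur-10179 (IV 14327393 to 14327416) lay 228 and 231 bp from the summit of a peak (signal 198) at the snoRNA gene Y67A10A.14, and the peaks near 21ur-5229 (signal 124), 21ur-53 (114) and 21ur-3160 (106) were at tRNA genes. The odds ratio was 0.515 with replicate 1 alone and 0.241 with 0.5 times the window, and the share of loci moved with the window, to 0.176% with 0.5 times the window and 0.670% with 2 times the window.

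On chromosome IV, 60 bins of 100 kb with at least 20 piRNA genes held 14345 of the 15363 piRNA genes. IDR peaks were found at 22.3 per Mb in these bins (134 peaks) and at 18.3 per Mb in the rest of the chromosome (210 peaks), and other candidates at 434 and 309 per Mb. The odds ratio of an IDR peak against another candidate was 0.869 (0.696 to 1.09, Fisher's exact p = 0.218), so no difference was detected. It was above 1, and did not pass the test, for the 838 peaks of highest signal (1.22) and with replicate 1 alone (1.18). The motif CTGTTTCA, found upstream of many piRNA genes, was within 100 bp of the summit at 15 of 1650 nuclear IDR peaks (0.909%) and in 1.61% of windows 500 bp to each side (ratio 0.566, exact McNemar p = 0.154). The ratio was 0.3 within 50 bp of the summit and 0.536 against windows 1000 bp to each side, and neither passed the test.

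**Figure D4:**
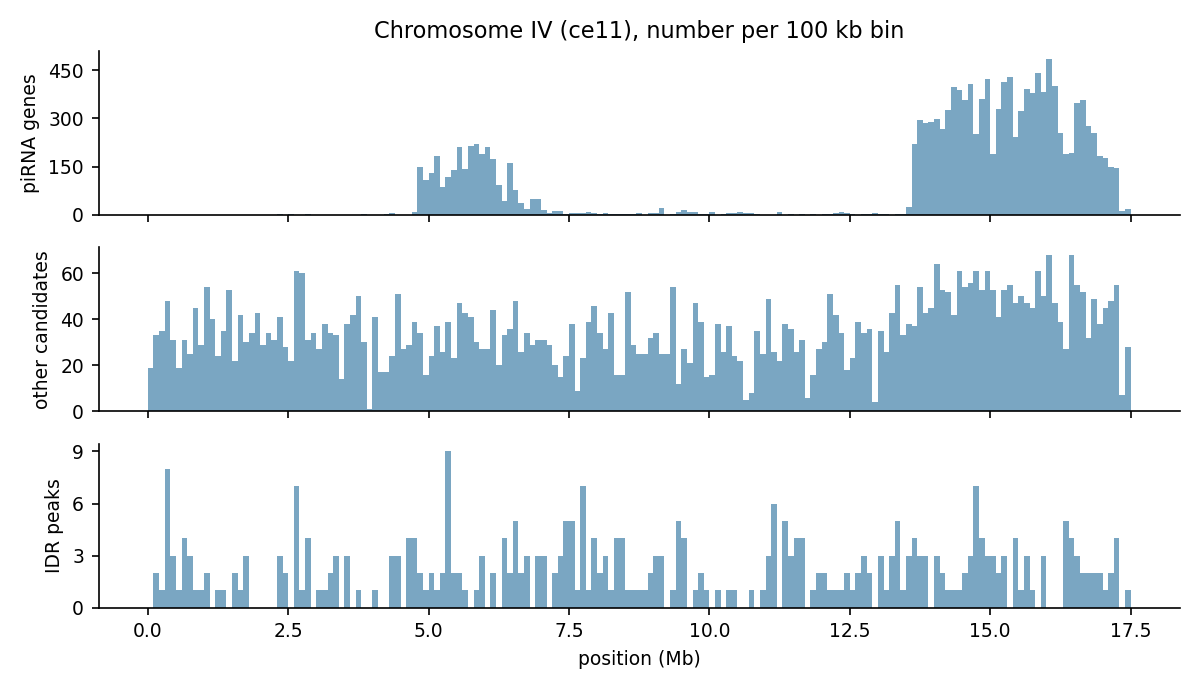
Bars give the number of piRNA genes, other pooled candidates and IDR peaks (y axes) in each 100 kb bin along chromosome IV (x axis, Mb, ce11). The other candidates were at 434 per Mb in the bins with at least 20 piRNA genes and 309 per Mb elsewhere, and IDR peaks at 22.3 and 18.3 per Mb.

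The B box, the internal promoter element bound by TFIIIC in tRNA genes, was present within 100 bp of the summit at 431 of 1650 nuclear IDR peaks (26.1%, 24.0 to 28.3%), against 8.73% of windows 500 bp to each side (2.99-fold, exact McNemar p = 3.87e-36, the larger of the p-values for the 2 sides). Of these 431 peaks, 305 were among the 317 peaks given to tRNA genes (96.2%, where flanking windows had 10.4%). The excess over all nuclear peaks therefore largely restates the tRNA class, whose genes carry this element. At snoRNA genes 32 of 86 peaks had the B box (37.2% against 11.0%, exact McNemar adjusted p = 0.0122 over 33 motif tests), and at protein-coding promoters 35 of 742 (4.72% against 7.88%, adjusted p = 0.309). No class other than tRNA and snoRNA genes passed this test, and peaks with no gene had 11.7% against 9.69%. The pattern searched was GWTCRANNC on either strand.

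Protein-coding promoters made up the largest class by number. A summit lay within 500 bp of an annotated 5′ end for 887 IDR peaks (52.9%) and 6683 other candidates (23.6%), an odds ratio of 3.64 (3.29 to 4.02, Fisher's exact test, adjusted p = 2.90e-137). Without regions at short RNA genes, an alternative chosen after seeing the data, it was 6.49. Of 19973 protein-coding genes 1187 (5.94%) had an IDR peak, a share that was 3.68% with a window of 250 bp and 7.78% with 1000 bp.

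Ribosomal protein genes and oogenesis genes had peaks at their promoters most often among the gene lists tested. Among the protein-coding genes with a pooled candidate at the promoter, 60 of 79 ribosomal protein genes had an IDR peak (75.9%) against 16.3% of the rest (odds ratio 16.3, 9.67 to 27.4, Fisher's exact test, adjusted p = 8.19e-30 over 17 lists). They included rpl-15, rpl-20, rpl-3 and rpl-35. The odds ratio was 6.12 with a window of 250 bp (19 of 36 genes), 39.6 with 1000 bp (70 of 79) and 47.6 with all protein-coding genes as the background. Of 16 oogenesis genes 12 had a peak (75%, odds ratio 14.9, 4.78 to 46.2, exact test, adjusted p = 4.18e-06). They were led by the eggshell chondroitin proteoglycan genes cpg-1 (signal 179, summit 255 bp upstream) and cpg-2 (110), egg-1 (124), which encodes an oocyte surface protein needed for fertilisation, and mex-5 (111), a regulator of embryonic polarity. The gene egg-1 has the close copy egg-2, so its value is uncertain. Without replicate 2 the list had 10 of 18 (55.6%, odds ratio 7.73, exact test, adjusted p = 0.000358), and its odds ratio was 9.81 with a window of 1000 bp and 23.1 with the 838 peaks of highest signal. Translation factor genes had 10 of 25 (40%, odds ratio 3.29, exact test, adjusted p = 0.0297), among them eef-1A.1 (signal 150), eif-3.C (109), eef-1G (105) and eef-2 (100.97). Their call was lost with replicate 1 alone (2.90, exact test, adjusted p = 0.0979), and the odds ratio was 7.59 with all protein-coding genes as the background. Histone genes had 7 of 16 (43.8%, odds ratio 3.83, exact test, adjusted p = 0.0463), at the divergent pairs his-67 and his-68 (signal 127) and his-59 and his-60 (84.8) among others. Each of these pairs shared a single peak, so the 7 histone genes rest on fewer peaks, although the test treats genes as independent. These genes are near-identical copies and their peaks are uncertain, and the call was lost in 5 of the alternatives run, among them with either replicate alone, with adjusted p from 0.131 to 0.343. In these the odds ratio was 3.58, 3.38, 3.17 and 3.08, and 1.71 with all protein-coding genes as the background, and it was 6.46, past the threshold, without regions at short RNA genes.

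The other lists did not pass the test. Heat shock and chaperone genes had 7 of 17 (41.2%, odds ratio 3.45, exact test, adjusted p = 0.0539), with cct-8 (signal 173), cct-5 (97.1), hsp-110 (84.1) and cct-1 (66.0) first. They passed with a 1000 bp window (exact test, adjusted p = 0.00301) and with the 838 peaks of highest signal (6 of 16, odds ratio 6.11, adjusted p = 0.0108), and had 2 of 11 once regions at short RNA genes were left out (odds ratio 1.22). piRNA pathway genes had 6 of 18 (odds ratio 2.46, adjusted p = 0.297, and 1.46 with a window of 250 bp), with hrde-1, ife-3, znfx-1 and deps-1 at signals of 89.9, 76.6, 66.2 and 60.4. Genes of SNAPc subunits and piRNA transcription factors had 2 of 11 (1.09, exact test, adjusted p = 1), namely snpc-3.4 (77.4) and snpc-1.2 (45.6). The odds ratio of this list was 2.05 without replicate 2, 1.79 with a window of 250 bp and 3.52 with all protein-coding genes as the background, and passed in none of these. Sex determination genes had 4 of 12 (2.46, exact test, adjusted p = 0.317), nos-3, sdc-1, gld-1 and fem-1. In the exact test their odds ratio was 1.17 without replicate 1 (2 of 11), 1.26 with the 838 peaks of highest signal (1 of 9) and 1.53 with a window of 250 bp. tRNA synthetase genes had 2 of 26, ears-2 and kars-1 (0.408, adjusted p = 0.566), and 4 of 25 without replicate 2 (1.17). Spermatogenesis genes had 1 of 8, spe-39 (0.701, exact test, adjusted p = 1), 0 of 9 with either replicate left out and 2 of 9 with a window of 1000 bp (1.39). Cuticle and hypodermal genes had 2 of 27, col-38 and col-85 (0.391, exact test, adjusted p = 0.566). Both peaks were assigned to short RNA genes, that of col-85 to a tRNA gene with the summit in an intron of col-85, and without such regions the list had 0 of 24 (exact test, adjusted p = 0.115). Its odds ratio was 0.807 with the 838 peaks of highest signal, 0.632 without replicate 1 and 0.254 without replicate 2, and a window of 250 bp gave 0 of 14. The muscle, intestine and neuron lists had 0 of 3, 0 of 5 and 0 of 7, the RNA polymerase III list 0 of 4 and the major sperm protein list 0 of 4, too few to detect a difference (exact test, adjusted p from 0.943 to 1). Without replicate 2 the neuron list had 1 of 8 (odds ratio 0.876). With all protein-coding genes as the background, heat shock (odds ratio 4.45, exact test, adjusted p = 0.00793), piRNA pathway (6.81, adjusted p = 0.00348) and sex determination genes (4.88, adjusted p = 0.0385) passed as enriched, and cuticle and hypodermal genes (0.188, adjusted p = 0.0132) as depleted. The pair snpc-1.3 and unc-119, entered as a list, had 0 of 2 (exact test, adjusted p = 1).

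Neither the tagged gene nor the marker gene often used to select such transgenes had an IDR peak. Around snpc-1.3 (V 5437084 to 5439168) the best of 6 candidates within 1000 bp ranked 3634 with a signal of 25.6. Around unc-119 (III 10902641 to 10908935) the best of 3 ranked 13535 with a signal of 14.2. No ChIP from a strain without the tag was analysed here, so enrichment at a class was measured against other candidates and shifted positions only.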

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

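The tests of coverage and of summits within 100 bp of tRNA genes were chosen after the mitochondrial peaks had been seen, the latter with its 50% bound set once the distances were known, and the test of summits inside tRNA genes before its result was known.

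IDR peaks on the mitochondrial genome numbered 26 of 28 mitochondrial candidates, and were singled out as a signal outside the nuclear classes; they entered the class comparisons only as regions outside every class. They included the 18 highest peaks, with a median signal of 560 and a maximum of 7841, against 411 for the highest nuclear peak, and the 2 strongest had summits in the coding sequences of WBGene00000829 (position 4756) and WBGene00010967 (position 12445). The peaks covered 46.2% of the 13794 bp genome, a value that follows from their number and width, so it does not decide whether many copies of mitochondrial DNA per cell, not fully balanced by the control, gave these peaks. Binding at mitochondrial tRNA genes was argued against as the source of most of these peaks, because only 4 of 26 summits (15.4%, Clopper-Pearson 95% interval 4.36 to 34.9%) lay within 100 bp of a tRNA gene. The 317 of 317 nuclear summits given to tRNA genes did so, but they were chosen for lying within 250 bp of one and are no independent benchmark. Such binding stays open for the 2 summits (7.69%, 0.946 to 25.1%) inside the 22 tRNA genes that make up 8.83% of the genome (exact binomial p = 1). The control library was not used here, and no biological explanation that the sample labels name was tested.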

How the results depend on the processing

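Alternatives without mitochondrial regions or without regions at short RNA genes were chosen after seeing the data. Of the alternatives of the main results, 105 kept the direction and the side of the threshold, or stayed within the range allowed for a value without a test, 6 moved, 3 gave a ratio on the other side of 1, 3 gained a call and 1 lost it. The enrichment of tRNA, snRNA, SL RNA, snoRNA and miRNA genes and promoters and the depletion of piRNA genes kept both in every alternative that left regions of the class to test. By construction, the list of highest signal held 838 peaks. Of lists called, 2 passed with replicate 1 alone and 4 in the main test (2 to 3 with either replicate left out). For tRNA pseudogenes the odds ratio was 2.95 with a window of 0.5 times the size, 4.84-fold over circular shifts, and 2.08 to 2.73 without either replicate. For rRNA genes the ratio to circular shifts was 0, a turn set by a count of 0 IDR peaks, since the odds ratio it turned from rested on the 0.5 added to empty cells, so it shows no reversal in the data. For piRNA bins the odds ratio turned to 1.22 with the 838 peaks and was 0.920 to 1.18 without either replicate. Shares with a peak moved to 0.176% and 0.670% for piRNA genes and to 3.68% and 7.78% for promoters with windows of 0.5 and 2 times the size, as wider windows must hold more. The odds ratio of X against autosomal tRNA genes lost its call at 1.31 with the narrower window. Among single lists, 91 alternatives kept direction and threshold, 6 lost the call, 6 gained it and 9 gave an odds ratio on the other side of 1 without passing. Those that turned were tRNA synthetases (1.06 with all genes as background; 0.501 to 1.17 without either replicate) and spermatogenesis genes (1.07 at 250 bp, 1.39 at 1000 bp). The 5 others counted there, RNA polymerase III (1.22 with all genes, 1.12 with the 838 peaks), major sperm proteins (1.78 at 250 bp, 1.12 with the 838 peaks) and muscle (1.44 with the 838 peaks), had 0 members with a peak in the main test and in these alternatives. Their odds ratios above 1 came from the 0.5 added to empty cells, and no direction turned. Beyond what is stated, the cause was not tested. The unknown read depth limits any statement on loci without a peak. No paired analysis was possible because there is 1 group.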

Other observations

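Chosen only after results were seen were the tests of the motif AACNNNNNNNNTGTC, of rank bands, of X against autosomes among unique loci and of local shifts with matched GC content.

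Many of the strongest short RNA loci carried a shared element resembling the proximal sequence element, the site that SNAPc binds. The pattern AACNNNNNNNNTGTC was found within 100 bp of the summit at 33 of 86 snoRNA peaks (38.4% against 3.49% in flanking windows, exact McNemar adjusted p = 2.50e-06 over 33 tests), at 16 of 33 snRNA peaks (48.5% against 3.03%, adjusted p = 0.00181) and at 8 of 14 SL RNA peaks (57.1% against 7.14%, adjusted p = 0.0737). Because the pattern was read from peaks of these classes, these shares are a description and not independent evidence. Of the 5 strongest miRNA loci it was found at the related pair cel-mir-8196b and cel-mir-8196a and not at cel-mir-5549, cel-mir-51 or cel-mir-4936: AACCCGCGAGGTGTC at X 14324561 to 14324575 upstream of cel-mir-8196b and AACCCGGCAGGTGTC at X 2328929 to 2328943 upstream of cel-mir-8196a. For comparison, AACCCGCGAGATGTC lay at III 11090951 to 11090965, upstream of sls-2.15, AACCCGCATGATGTC at I 2688891 to 2688905, upstream of the U5 gene F32B5.9, and AACCCGACTCATGTC at V 8500499 to 8500513, upstream of the snoRNA gene ZK994.7. Of the 5 strongest snoRNA loci 5 had a match, of the 5 strongest SL RNA loci 3, and of the 5 strongest snRNA and miRNA loci 2 each. Matches at tRNA peaks (1.89% against 2.37%), protein-coding promoters (1.62% against 2.09%) and peaks with no gene (5.10% against 4.08%) did not exceed their flanks by the exact McNemar test (adjusted p = 1 for each). The gene for the RNA of RNase P, rpr-1 (I 13463955 to 13464207), had an IDR peak of signal 146, while the Y RNA gene yrn-1 had none and its best candidate ranked 2457; both were chosen after their values were seen.

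Low-ranked candidates lay near piRNA genes more often than IDR peaks did. The share of pooled candidates with a summit within 250 bp of a piRNA gene was 2.45% among the 1676 IDR peaks, 3.61% for ranks 1677 to 5000, 6.58% for the next ranks up to 10000, 7.74% for ranks 10001 to 15000 and 6.16% for ranks 25001 to 30000. The 1820 low-ranked candidates exceeded the 1270 given by circular shifts (1.43-fold, permutation adjusted p = 0.00036). An excess over shifts was not particular to piRNA genes: low-ranked candidates were 2.33-fold over shifts at tRNA pseudogenes, 1.958-fold at tRNA genes, 1.72-fold at snoRNA genes and 1.26-fold at protein-coding promoters (permutation adjusted p = 0.00036 for each), and 1.83-fold at snRNA genes (adjusted p = 0.0021).

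Of 2605 low-ranked summits in the piRNA-rich bins of chromosome IV, 674 lay within 100 bp upstream of a piRNA gene, against 509 after moving each by 1 to 5 kb, a ratio of 1.32 (1.23 to 1.43, permutation p = 0.0002, the smallest that 10000 shifts can give). These limits, and those for matched GC below, hold the spread of the shifted counts only, not the counting error of the observed number. Reads shared between copies were argued against as the source of most candidates near piRNA genes, because only 2.47% of these had under 80% unique 31-mers. The other low-ranked candidates had 3.396% (odds ratio 0.721, 0.533 to 0.977, Fisher's exact p = 0.0361), so the excess predicted for shared reads was absent. That comparison alone cannot decide, since uniqueness can differ between such loci whatever placed the candidates. GC content remains open. The first test of it, stated in advance, gave what was predicted for a cause (median GC 28.6% against 33.7%, a difference of -5.07 percentage points). It compared candidates near piRNA genes with the others, and base composition can differ between such loci whatever placed the candidates. That first test therefore cannot decide whether GC content was a cause. Local shifts of matched GC were chosen after the result of that first test, and worded as a test of the whole cause only once their ratio was known. They lowered the ratio from 1.32 to 1.17 (1.098 to 1.25, permutation p = 0.0002), with a lower limit that does not clear the bound of 1.1 set for it. An excess therefore remained with GC matched, and GC content may account for part of it. Whether GC content accounts for all of the excess was not decided by that bound. In a search outside the planned tests, CTGTTTCA lay within 100 bp of the summit at 580 of 1820 low-ranked candidates near piRNA genes (31.9%). Windows 500 bp to each side had 22.1% (exact McNemar p = 9.73e-11, the larger of 2). At the 26502 others the shares were 1.06% and 1.21% (exact McNemar p = 0.196). The candidates near piRNA genes were picked for their position and the flanks were not, so the excess cannot tell binding from position. Weak occupancy of single piRNA promoters is a hypothesis beside GC content, and accessible chromatin, with no ChIP from an untagged strain used here, was not tested.

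Among 129 snRNA and SL RNA loci, 38 of 78 with at least 80% unique 31-mers had a peak and 8 of 51 others did (odds ratio 5.11, 2.13 to 12.3, Fisher's exact p = 0.000143), but SL RNA genes carried this difference. They had 14 of 17 and 0 of 13, nearly all of it SL2 against SL1 genes, so kind and uniqueness cannot be told apart there, and snRNA genes alone did not pass (24 of 61 against 8 of 38, odds ratio 2.43, 0.956 to 6.19, exact p = 0.0775). Shared reads therefore stay open as a possible explanation for these loci; outside them, tRNA genes differed (325 of 518 against 24 of 94, odds ratio 4.91, exact p = 2.84e-11), and no difference was detected at snoRNA genes (82 of 316 against 6 of 30, odds ratio 1.40, exact p = 0.661). Among loci with at least 80%, U6 genes had a peak less often than U1, U2, U4 and U5 genes (3 of 13 against 16 of 26, odds ratio 0.188, 0.0413 to 0.851, exact p = 0.0407), although U2 genes had 1 of 5. The share was taken over the gene with 250 bp to each side, so a short gene with copies elsewhere can pass 80%. This test therefore cannot part a difference between kinds from shared reads, and such a difference is only a hypothesis.

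The X against autosome odds ratio of tRNA genes was 1.45 (1.01 to 2.09, Fisher's exact p = 0.0448) among loci with at least 80% unique 31-mers, again with loci treated as independent. The share counts the 250 bp flanks as well, so tRNA genes with copies elsewhere can pass 80%. This comparison therefore does not remove reads shared between tRNA genes.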
